A study of Mus musculus with 8 samples.

How the data were processed

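Single-nucleus RNA-seq libraries from the ventral hippocampus of male mice aged 8 to 12 weeks were compared between a D1-Cre and a D2-Cre driver line, 4 libraries per line (replicates A to D). In both lines Cre turned on eGFP::L10a, a ribosomal protein fused to a green fluorescent protein, so that nuclei could be sorted by fluorescence. Per the labels' protocols, GFP-positive nuclei were recovered by sorting, 8000 per sample were loaded on 1 lane, and 10x Genomics 3' libraries were made. The deposited values were UMI counts per gene and barcode. Per the submitters' processing notes, Cell Ranger 3.1.0, Seurat 4.3.0 and mm10 were used; the roles of the last 2 are not stated there.

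The deposited counts were used as they were, and every value below was computed from them. Gene names and Ensembl IDs were taken as paired in the files, and positions (GRCm38/mm10) came from GENCODE vM21 by Ensembl ID, with 30934 of 31053 IDs matched. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

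The tables held 4640 to 71929 barcodes per library, more than the 8000 nuclei loaded in 6 of the 8 libraries. Barcodes with at least 800 genes and under 5% of UMIs from mitochondrially encoded genes were kept, at most the 8000 with the most UMIs per library. Scrublet, as built into scanpy, was run per library with an expected doublet rate of 0.06. It called 0.0500% to 1.30% of barcodes, under 0.5% in 5 of 8 libraries, so doublets were hardly removed. At 800 genes the limit of 8000 barcodes, and an alternative limit of 5000, removed no nucleus; at the alternative minimum of 500 genes the limit of 8000 cut D2 B.

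Counts of the kept nuclei were scaled to 10000 UMIs and log-transformed. The 3000 most variable genes, chosen within libraries and without Drd1 and Drd2, gave 40 principal components and a shared-neighbour graph of 20 neighbours, which Leiden clustering split at resolution 1 without batch integration. Marker lists fixed beforehand gave each cluster a broad class, and excitatory and inhibitory clusters a subclass. A cluster took the class with the largest share of its markers detected (at least 0.5 of the highest cluster level on a scale with a 10 CPM pseudocount, and at least 20 CPM). It needed at least 3 detected markers and a gap of 0.05 to the next class, and was kept out where another class led its 10 highest genes. This naming rule was settled after the clusters and their library counts had been seen, after an earlier exploratory clustering and other forms of the rule, and partly because 1 cluster looked like mossy cells and another like a mixture. Of 28 clusters, 26 took a name. Class names end in "-like" because they rest on markers alone. No oligodendrocyte or microglia class was found, so background was read from the barcodes past UMI rank 8000, called the plateau here; D2 C and D had none.

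The library was the replicate, and differences are D1 minus D2. UMI counts were summed per library over all nuclei, excitatory and inhibitory nuclei, and each subclass with at least 20 nuclei in at least 3 libraries per line. D1 and D2 were compared with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment), and a gene passed at an adjusted p under 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic, and left out where F was close to 0. The difference between classes was tested as a class by line interaction with the library as a block. Shares and receptor levels were compared with a 2-sided exact permutation test over 70 assignments of 4 against 4 libraries, whose smallest p is 0.0286, adjusted within each family of tests. UMI-positive shares were taken after thinning each nucleus to 1000 UMIs. Gene lists, 45 in number, were compared with camera (limma, preset correlation 0.01, log CPM with a prior count of 3, lists of at least 3 tested genes) and again with an estimated correlation. CPM beside fold changes are TMM-scaled, and those of the receptor comparison and the plateau are plain CPM.

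The nuclei filter, clustering settings, markers, gene lists, comparisons, tests, rule for named genes and 9 kinds of alternative were fixed before the data were examined. The rule named Drd1 to Drd5, the 10 passing genes (5 in a subclass) with the largest fold change in each direction at 20 CPM or more without overlap between the lines, leaving out clone-style names, and up to 3 members of each list. Of the genes it named, 1 is not reported here and is not among the counts of alternatives. Drd3, Drd4 and Drd5 had too few UMIs to be tested in any set. List members printed below were picked from those after their values were seen, mostly ones whose call held under every alternative. Gm4894 and 5 genes with opposite differences were chosen outside the rule, after their values were seen. The Pvalb and Sst clusters, MGE clusters of over 500 nuclei with these genes among their detected markers, were also made sets of their own after the clusters had been seen.

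The alternatives fixed beforehand were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, at least 500 or 1200 genes per nucleus, at most 5000 barcodes, called doublets kept, classes from marker scores, an estimated list correlation, no thinning, the replicate letter as a block, and leaving out each library. Nuclei below 800 genes took the class of the nearest cluster centroid, which gave the clustered class in 89.0% of nuclei above it. Added after the data were seen were a library-specific UMI minimum (1.2 times the UMIs of the first barcode past rank 8000, so none in D2 C and D, which had no such barcode), all clusters of a name, only the libraries with more than 8000 barcodes, subtraction of the plateau profile, and thinning of libraries to equal depth. All were run before the replicate letters were checked for pairing and before the tests of explanations were chosen, except that 3 of those tests were set down before their result was seen.

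The gene tests were tested on simulated data with 200 changed genes, drawn from the means and library sizes of each comparison, after a first run on the real counts. At a log2 fold of 1 they recovered 75% in all nuclei, 82% in excitatory nuclei, 84% in inhibitory nuclei, 88% in MGE-derived interneuron-like nuclei, 84% in CGE-derived interneuron-like nuclei, 46% in CA1-like nuclei, 84% in the Pvalb clusters and 78% in the Sst clusters. At a log2 fold of 2 they recovered 95 to 100% in the 8 comparisons. Unchanged genes made up 8.5% in all nuclei, 5.3% in excitatory nuclei, 3.7% in inhibitory nuclei, 10.5% in MGE-derived interneuron-like nuclei, 4.2% in CGE-derived interneuron-like nuclei, 2.1% in CA1-like nuclei, 5.7% in the Pvalb clusters and 4.8% in the Sst clusters of the calls.

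Kept nuclei held 1089615 to 16171483 UMIs per library. Intervals from counts cover counting error only. D2 C and D were deeper, their tables held no barcode under 769 UMIs, and whether they were processed apart is not given in the sources used here. Any such difference would lie within D2 alone, so comparisons were repeated in the other 6 libraries, where the smallest exact p of 4 against 2 is 0.0667. Unnamed clusters, and classes without enough nuclei per library, were left out of the comparisons of classes.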

Results

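The data were UMI counts from 8 single-nucleus libraries of the ventral hippocampus, 4 from the D1-Cre line and 4 from the D2-Cre line (replicates A to D). These drivers mark cells by the genes of the dopamine receptors D1 and D2. In order of replicate, the D1 tables held 27830211, 33942836, 30563305 and 15888760 UMIs and those of D2 35178985, 49181976, 13720591 and 16993396. The filters kept 683, 1340, 1938 and 2208 D1 nuclei and 1228, 3291, 4015 and 4905 D2 nuclei, 19608 in all. Median depth was 1461 to 1627 UMIs per nucleus in the D1 libraries and 1417 to 2789 in the D2 libraries, with D2 C and D the deepest. Shares and CPM are given as mean ± SD over 4 libraries per line, and log2 fold changes (D1 minus D2) as estimate ± SE from edgeR over the same libraries, unless another n is stated.

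The first comparison asked which classes of neurons each driver marked. Nuclei named deep cortical layer-like, from clusters with the deep-layer markers Ctgf, Cplx3, Foxp2 and Tle4, made up 57.2 ± 5.05% in D1 and 0.765 ± 0.497% in D2 of excitatory nuclei. CA1-like nuclei made up 9.40 ± 3.53% in D1 and 51.5 ± 2.03% in D2, and mossy cell-like nuclei, with the markers Calb2 and Csf2rb2, 4.16 ± 3.75% in D1 and 20.2 ± 6.24% in D2. Among inhibitory nuclei, interneurons like those derived from the medial ganglionic eminence (MGE) made up 81.9 ± 2.91% in D1 and 57.5 ± 4.41% in D2, and those like caudal (CGE) ones 12.9 ± 2.07% in D1 and 38.8 ± 3.27% in D2. Nuclei of the Pvalb clusters, an interneuron group named for the calcium buffer parvalbumin, made up 53.4 ± 2.65% in D1 and 27.9 ± 4.77% in D2. The Sst clusters, named for somatostatin, made up 27.9 ± 2.53% in D1 and 25.5 ± 1.71% in D2.

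Each of these differences but that of the Sst clusters had an exact p of 0.0286 (2-sided permutation, the smallest possible with n = 4 per line), with all 4 D1 libraries on the same side of all 4 D2 libraries. After adjustment over 9 tests p was 0.0514, and 0.0571 over the 2 tests of the added sets, so no share passed. The other exact permutation p values were 0.171 for the Sst clusters, 0.143 for excitatory nuclei (37.7 ± 17.8% in D1 and 52.3 ± 1.99% in D2 of named nuclei) and 0.0857 for inhibitory nuclei (56.1 ± 20.4% in D1 and 32.5 ± 7.26% in D2). Dentate granule-like nuclei made up 2.50 ± 2.76% in D1 and 0.298 ± 0.176% in D2 of excitatory nuclei (exact p 0.343), and Cajal-Retzius-like nuclei were 0% of named nuclei in D1 and 1.22 ± 0.981% in D2 (exact p 0.143). In the 4 D1 libraries with D2 A and B alone, the differences in percentage points were 56.5 for deep cortical layer-like, -43.7 for CA1-like, -19.6 for mossy cell-like, 21.8 for MGE, -24 for CGE and 22 for Pvalb nuclei. Each had an exact permutation p of 0.0667, the smallest possible there; the differences were -13.4 for excitatory, 28 for inhibitory, 3.80 for Sst, 2.35 for dentate granule-like and -0.488 for Cajal-Retzius-like nuclei. The MGE, CGE, CA1-like, mossy cell-like and deep cortical layer-like shares passed without D1 D (adjusted p 0.0367), as did the excitatory and inhibitory shares, or without D2 A (0.0429), as did the Cajal-Retzius-like share, and with at least 500 genes per nucleus 10 shares passed (adjusted p 0.0286 to 0.0321). With classes from marker scores 6 shares passed (adjusted p 0.0429) but the differences shrank to 20 for deep cortical layer-like, -9.66 for CA1-like and -14.5 for CGE nuclei, from 56.4, -42.1 and -25.9.

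**Figure D1:**
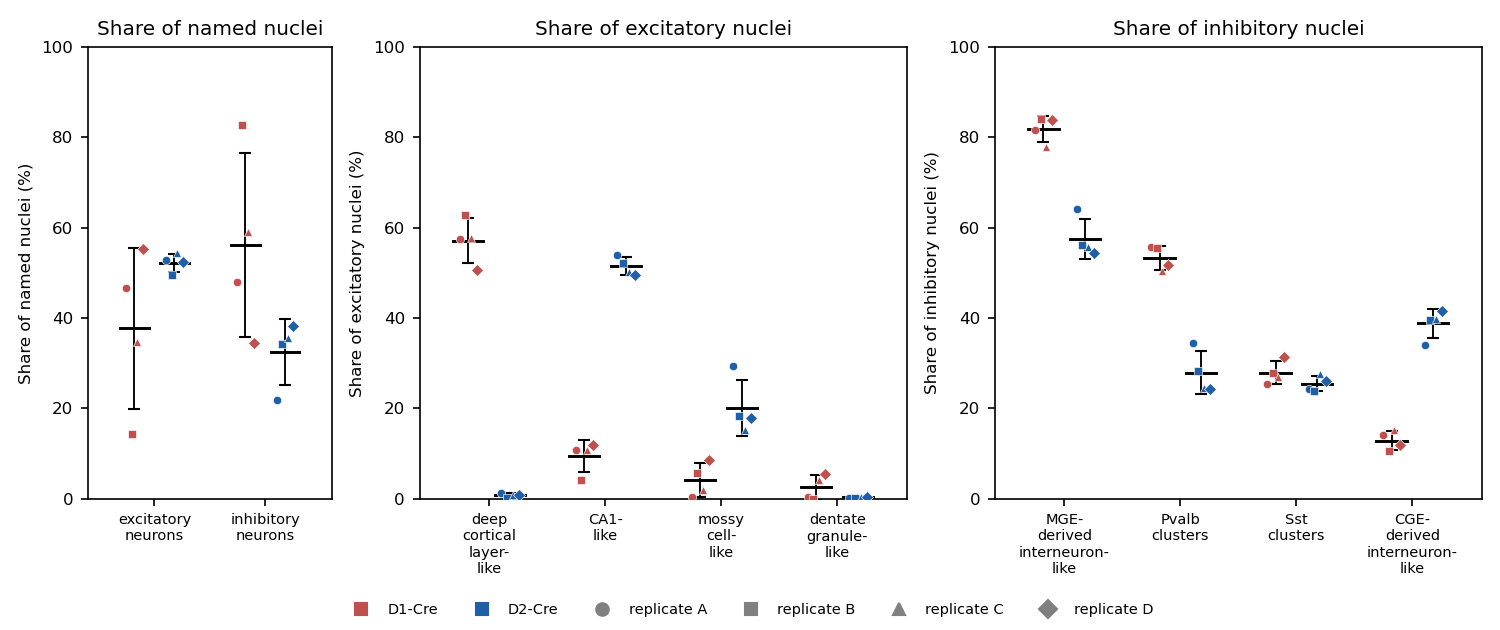
Share of nuclei per library (percent, vertical axis) in each class (horizontal axis), with D1-Cre in red, D2-Cre in blue, marker shape for the replicate and bars for mean ± SD of 4 libraries. The D1 libraries had 50.5 to 62.8% deep cortical layer-like nuclei among excitatory ones, and the D2 libraries 49.5 to 54.1% CA1-like ones.

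The next comparison asked whether the receptor gene of each driver was found in the nuclei it sorted, which also checks the labels. The D1 receptor gene Drd1 (ENSMUSG00000021478, chromosome 13, 54051183 to 54055705) stood at 75.5 ± 11.9 CPM in D1 and 1.98 ± 0.902 CPM in D2 over all nuclei. In inhibitory nuclei it stood at 102 ± 5.85 CPM in D1 and 1.23 ± 1.25 CPM in D2, in the Pvalb clusters at 109 ± 10.1 CPM in D1 and 1.77 ± 2.07 CPM in D2 and in the Sst clusters at 107 ± 19.5 CPM in D1 and 0.623 ± 0.758 CPM in D2. Excitatory nuclei had 45.1 ± 8.17 CPM in D1 and 2.64 ± 0.703 CPM in D2, and CGE nuclei 63.6 ± 35.7 CPM in D1 and 1.33 ± 1.55 CPM in D2. The D2 receptor gene Drd2 (ENSMUSG00000032259, chromosome 9, 49340627 to 49408177) stood at 4.46 ± 1.12 CPM in D1 and 237 ± 4.03 CPM in D2 over all nuclei. Its level was 4.24 ± 1.56 CPM in D1 and 277 ± 12.8 CPM in D2 in excitatory nuclei, 4.38 ± 1.33 CPM in D1 and 180.3 ± 12.5 CPM in D2 in inhibitory nuclei and 2.08 ± 3.61 CPM in D1 and 238 ± 14 CPM in D2 in CA1-like nuclei, where 3 D1 libraries had enough nuclei. MGE nuclei had 108 ± 6.09 CPM in D1 and 1.13 ± 1.08 CPM in D2 for Drd1 and 4.60 ± 1.83 CPM in D1 and 199 ± 18.4 CPM in D2 for Drd2.

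For Drd2, CGE nuclei had 3.12 ± 6.25 CPM in D1 and 154 ± 9.37 CPM in D2, the Pvalb clusters 1.66 ± 2.73 CPM in D1 and 142 ± 14 CPM in D2 and the Sst clusters 9.64 ± 1.22 CPM in D1 and 255 ± 34.8 CPM in D2. Every one of these differences had an exact permutation p of 0.0286 and an adjusted p of 0.0312 (12 tests) or 0.0286 (4 tests of the added sets), with no overlap between the lines. The exception was Drd1 in CA1-like nuclei, at 18.5 ± 17.1 CPM in D1 and 2.47 ± 0.976 CPM in D2 (exact p 0.143, 3 against 4 libraries). Within the 6 libraries without D2 C and D the Drd1 difference over all nuclei was 74.2 CPM and the Drd2 difference -234 CPM. The exact permutation p there was 0.0667, the smallest possible, in all sets but CGE for Drd1 (0.133) and CA1-like for Drd1 (0.400) and Drd2 (0.100, the smallest with 3 against 2 libraries). Leaving out any 1 D2 library, the adjusted p of Drd1 in CGE nuclei was 0.0686, and leaving out any 1 of the 7 libraries that of Drd2 in CA1-like nuclei was 0.0667 to 0.109. That last test could not pass with the 2 against 4 or 3 against 3 libraries left, and its difference stayed at -241 to -229.8 CPM. After thinning to 1000 UMIs, 6.77 ± 1.68% of D1 nuclei held a Drd1 UMI against 0.0975 ± 0.0818% of D2 nuclei. A Drd2 UMI was found in 19.9 ± 0.432% of D2 nuclei and 0.450 ± 0.139% of D1 nuclei. The plateau barcodes held Drd1 at 11.8 to 14.3 CPM in D1 and Drd2 at 212 and 208 CPM in D2 A and B, so a UMI does not by itself show a nucleus to express the gene. Plateau UMIs at these levels, computed after the levels were seen, gave 4.3 to 4.7% of the Drd1 UMIs of D1 nuclei by library, and 25.6 to 29.3% of the Drd2 UMIs of D2 nuclei in D2 A and B (21.2 to 21.9% in excitatory and 35.8 to 44.8% in inhibitory nuclei).

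**Figure D2:**
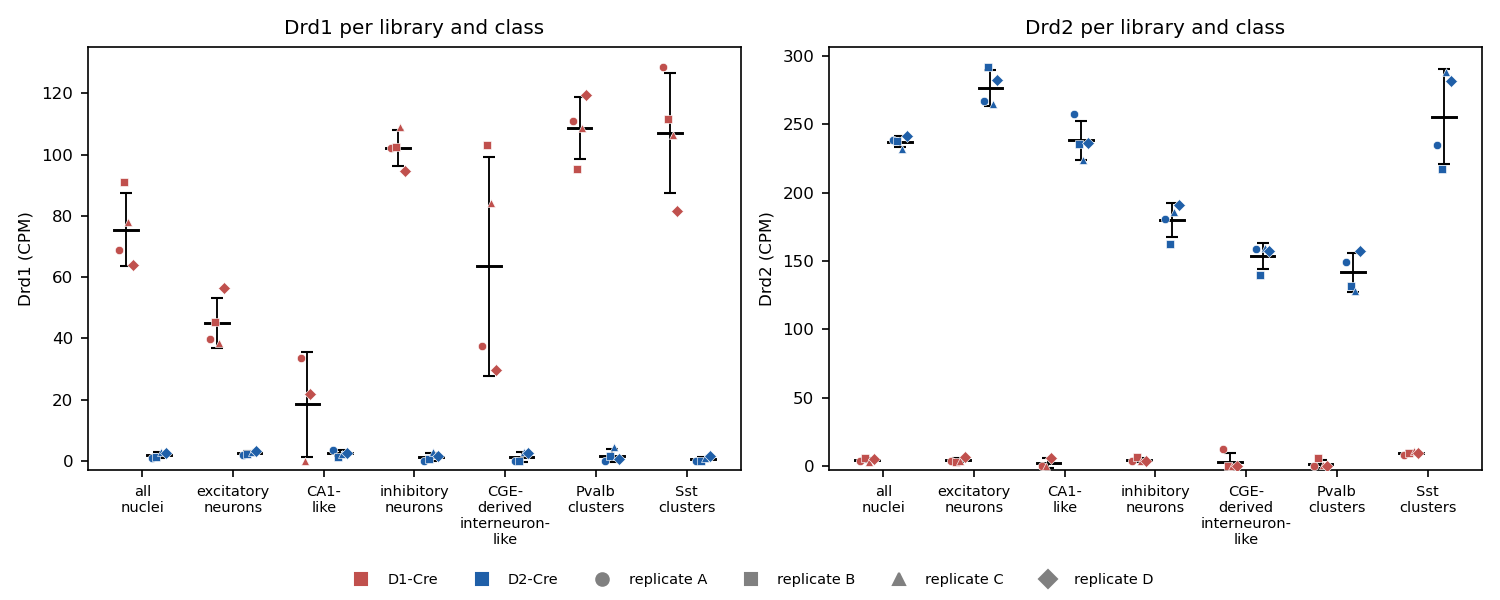
Plain CPM (vertical axis) of Drd1 (left) and Drd2 (right) per library in each set of nuclei (horizontal axis), with D1-Cre in red, D2-Cre in blue, marker shape for the replicate and bars for mean ± SD. Over all nuclei Drd1 lay between 64 and 91.1 CPM in D1 libraries and Drd2 between 232 and 241 CPM in D2 libraries.

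Genes next to the receptors were compared to ask whether the difference stopped at the receptor gene. Sfxn1 (ENSMUSG00000021474, chromosome 13, 54071869 to 54108342) codes for a mitochondrial serine transporter and lies 16164 bp from Drd1. It was higher in D1 by 1.89 ± 0.12, at 138 ± 20.1 against 37 ± 2.79 CPM. Ttc12 (ENSMUSG00000040219, chromosome 9, 49436963 to 49486225), 28786 bp from Drd2, codes for a tetratricopeptide repeat protein and was lower in D1, with a log2 fold change of -5.54 ± 0.40 and 0.254 ± 0.297 against 13.9 ± 1.28 CPM. Gm4894 (ENSMUSG00000054156, chromosome 9, 49250531 to 49280594), 60033 bp from Drd2, had 0 CPM in all 4 D1 libraries and a mean of 11.7 CPM in D2. Their edgeR adjusted p values were 3.77e-06 for Sfxn1, 6.26e-06 for Ttc12 and 5.31e-05 for Gm4894. Ncam1, an adhesion molecule within 200 kb of Drd2, did not pass (0.01 ± 0.09, edgeR adjusted p 0.973). Neither did Gm11149, which lies antisense within Ncam1 and shares its position (0.00, with an SE too unstable to give, adjusted p 0.999), nor the histamine receptor gene Hrh2 near Drd1 (0.46 ± 0.17, adjusted p 0.0823). Hrh2 was higher in D1 in inhibitory nuclei (0.49, edgeR adjusted p 0.0116) and CGE nuclei (1.58, adjusted p 4.9e-07), and stood at -0.50 in excitatory nuclei (adjusted p 0.0918) and -0.77 in CA1-like nuclei (adjusted p 0.439).

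**Figure D3:**
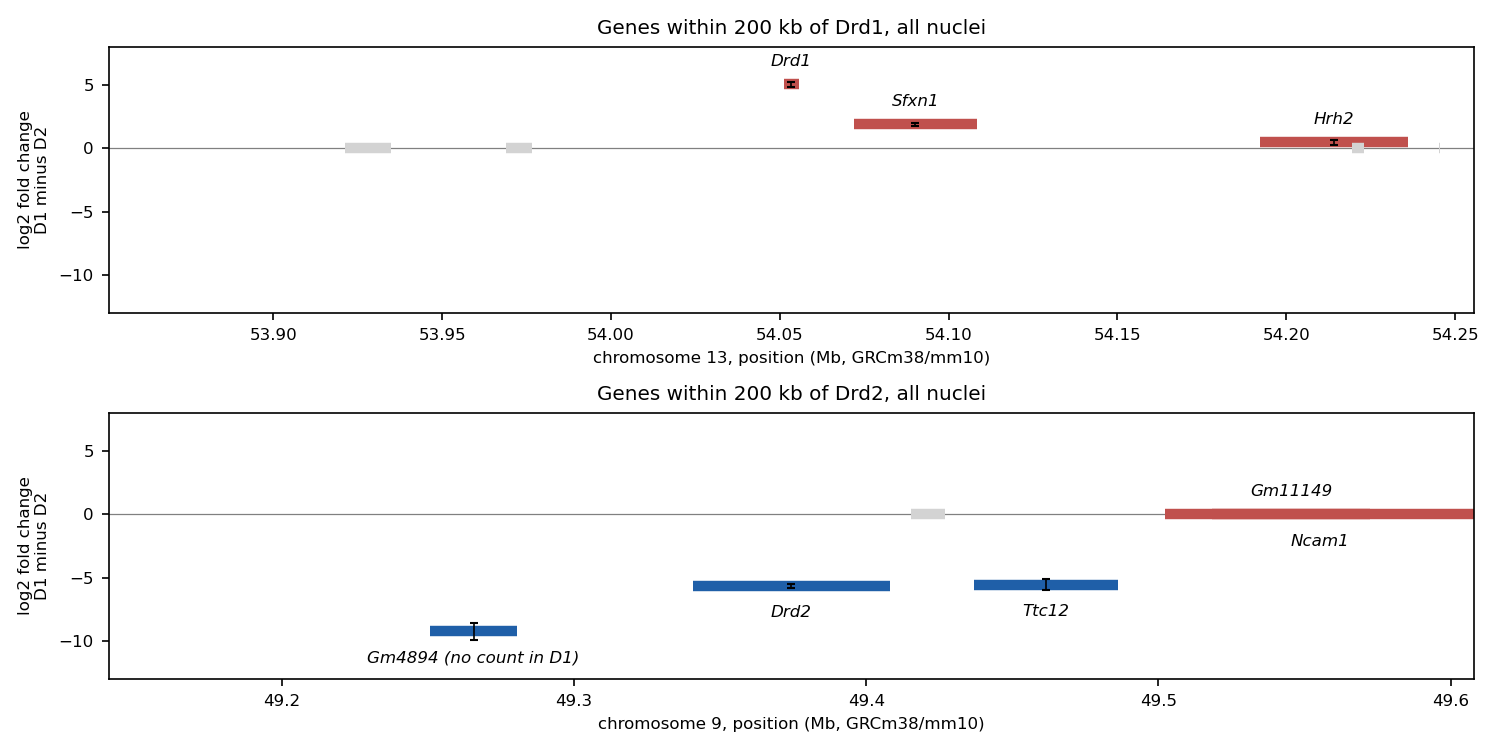
Log2 fold change, D1 minus D2, over all nuclei (vertical axis) of the tested genes within 200 kb of Drd1 (top) and Drd2 (bottom), with grey bars at 0 for genes not tested and each bar spanning the gene on GRCm38/mm10 (Mb, horizontal axis) and error bars for SE. Sfxn1 lay above 0 beside Drd1, and Ttc12 and Gm4894 lay below 0 beside Drd2, while Ncam1 lay at 0.01; Gm4894 had no count in D1, so its fitted position is not a measured fold.

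The comparison over all nuclei asked which transcripts separated the sorted populations as wholes, cell classes included. Of 11822 genes tested, 1862 passed, 965 higher and 897 lower in D1. Ctgf (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683) codes for a secreted matricellular protein of deep cortical neurons and was higher by 6.37 ± 0.62 (25.1 ± 15 against 0.416 ± 0.447 CPM). Nxph3, a ligand of alpha-neurexins, was higher by 5.58 ± 0.38 (22.1 ± 8.20 against 0.425 ± 0.194 CPM). Pappa2, a protease of insulin-like growth factor binding proteins, was higher by 5.06 ± 0.54 (28.5 ± 17 against 1.07 ± 0.392 CPM). Foxp2, a transcription factor of deep cortical layers, was higher by 2.40 ± 0.22 (28.3 ± 8.01 against 5.11 ± 1.06 CPM). On the other side, Wfs1 (ENSMUSG00000039474, chromosome 5, 36966104 to 36989205), an endoplasmic reticulum protein and CA1 marker, had a log2 fold change of -3.63 ± 0.19 (1.78 ± 0.223 against 22 ± 0.493 CPM). Cdc14a, a phosphatase, had a log2 fold change of -3.85 ± 0.17 (4.04 ± 0.523 against 57 ± 6.87 CPM). Ndnf, a secreted neurotrophic factor, had a log2 fold change of -3.08 ± 0.21 (4.91 ± 1.49 against 41.4 ± 5.85 CPM). Bace2, a membrane protease, had a log2 fold change of -2.80 ± 0.23 (2.86 ± 1.47 against 22.9 ± 2.92 CPM). These genes did not overlap between the 4 D1 and 4 D2 libraries, with edgeR adjusted p values of 5.36e-08 to 0.000105.

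Among the fixed lists, deep cortical layer markers were higher in D1 (3 higher of 4 tested, the same number adjusted over the list alone; camera adjusted p 0.00170, and 0.171 with an estimated correlation). Besides Ctgf and Foxp2, the corepressor gene Tle4 was higher by 1.70 ± 0.19. CA1 markers were lower (3 lower of 5 tested, list alone the same, camera adjusted p 0.00362, and 0.171 with an estimated correlation). Fibcd1 stood at -2.34 ± 0.33. Mossy cell markers were lower (3 lower of 5 tested, list alone the same, camera adjusted p 0.00693, and 0.387 with an estimated correlation). The calcium buffer Calb2 stood at -2.13 ± 0.40 and the adhesion-related Ajap1 at -1.26 ± 0.12. Markers of MGE interneurons were higher (5 higher of 8 tested, 7 higher adjusted over the list alone; camera adjusted p 0.00170, and 0.511 with an estimated correlation). Inhibitory neuron markers were higher as well (3 higher of 8 tested, 4 higher adjusted over the list alone; camera adjusted p 0.00453, and 0.511 with an estimated correlation). The neuregulin receptor Erbb4 stood at 1.17 ± 0.21 and the neurexin ligand Nxph1 at 1.08 ± 0.21. Ventral hippocampus genes were lower (1 higher, 8 lower of 11 tested, list alone the same, camera adjusted p 5.59e-05, 0.387 with an estimated correlation). Examples were the matrix proteoglycan Dcn at -2.37 ± 0.26 and the glypican Gpc3 at -2.31 ± 0.21. Each was among the 10 highest genes of a CA1-like cluster, so the list follows class make-up too and does not show position.

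Axon guidance genes went both ways over all nuclei (4 higher and 13 lower of 30 tested, 4 higher and 14 lower adjusted over the list alone; camera adjusted p 0.00673, and 0.511 with an estimated correlation) for a shift down. The ephrin receptor Epha4 stood at -1.60 ± 0.21 and the semaphorin Sema3c at 1.78 ± 0.20. Cajal-Retzius markers were lower (3 lower of 3 tested, list alone the same, camera adjusted p 0.000545, and 0.171 with an estimated correlation). Some calls counted in these lists ended on the way from 8 libraries to plateau subtraction in 6 (8-library folds and edgeR adjusted p in parentheses). Subtraction took Trp73 (-2.51 ± 0.36) from -1.93 ± 0.41 (0.0220) to -1.82 ± 0.50 (0.0576), Dlx1 (1.25 ± 0.20) from 1.11 ± 0.27 (0.0369) to 1.03 ± 0.29 (0.0657) and Sst (1.29 ± 0.24) from 1.32 ± 0.33 (0.0460) to 1.11 ± 0.37 (0.111), the folds being smaller and the SEs larger. Leaving out D2 C and D ended the call of Reln (-0.94 ± 0.19) at -0.79 ± 0.22 (0.0611) and, subtracted, -0.66 ± 0.25 (0.171). It ended that of Lhx6 (1.14 ± 0.27) at 1.10 ± 0.37 (0.121) and, subtracted, 0.96 ± 0.39 (0.203). Man1a, Jun and Nr4a2 passed neither way (0.105 to 0.428). 5 other lists passed with the preset correlation, as higher and lower members (list alone) excitatory neuron markers 0 and 3 of 8 (the same), subiculum markers 0 and 2 of 3 (the same), direct-pathway genes 2 and 0 of 4 (the same), immediate early genes 1 and 1 of 14 (1 and 2) and dorsal hippocampus genes 0 and 2 of 5 (0 and 3), with camera adjusted p values of 0.00819 to 0.0327 and 0.171 to 0.601 with an estimated correlation. The direct-pathway list held Drd1 and Sfxn1 as its 2 higher genes, so its rise restates the sort. 632 genes passed (317 higher, 315 lower) in the 4 D1 libraries with D2 A and B alone. Leaving out 1 library left 1072 without D1 C, 1055 without D2 C and 1229 without D2 D.

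Within excitatory nuclei the question was which transcripts differed once inhibitory nuclei were set aside. The lines lay mostly in different clusters, with 1306 D1 and 46 D2 nuclei in the deep cortical layer-like one and 22 and 2 D1 against 1258 and 1191 D2 nuclei in 2 CA1-like ones. The values therefore also compare clusters: Ctgf, Pappa2, Cobll1, Galnt10 and Cdh18 were among the 10 highest genes of the deep cortical layer-like cluster. Of 10221 genes tested, 1916 passed, 991 higher and 925 lower in D1. Ctgf, Nxph3 and Pappa2 had log2 fold changes of 7.54 ± 0.36, 6.55 ± 0.26 and 6.37 ± 0.36. Cobll1, an actin-related gene, was higher by 5.27 ± 0.24 (96.2 ± 24.8 against 2.08 ± 1.16 CPM). Col8a1, a collagen, was higher by 5.06 ± 0.28 (33.5 ± 9.76 against 1.00 ± 0.117 CPM). Galnt10, a glycosyltransferase, was higher by 3.82 ± 0.15 (194 ± 34.4 against 13.9 ± 1.89 CPM). Pth2r, a peptide hormone receptor, was higher by 4.08 ± 0.34 (22.9 ± 8.21 against 1.37 ± 0.771 CPM). Tcf7l1, a transcription factor of the Wnt pathway, had a log2 fold change of -4.25 ± 0.34 (0.832 ± 0.962 against 26 ± 1.88 CPM). The estrogen receptor gene Esr2 stood at -2.55 ± 0.30 (3.43 ± 2.64 against 28.2 ± 4.34 CPM) and the prolactin receptor gene Prlr at -2.51 ± 0.30 (3.75 ± 2.82 against 25.8 ± 2.99 CPM). Pbx3, a homeobox transcription factor, had a log2 fold change of -2.45 ± 0.20 (24.5 ± 8.77 against 113 ± 11.2 CPM). The edgeR adjusted p values of the last 8 genes were 3.13e-11 to 1.32e-05, without overlap between the lines.

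Deep cortical layer markers were higher in D1 excitatory nuclei (5 higher of 5 tested, the same number adjusted over the list alone; camera adjusted p 7.36e-09, and 0.0235 with an estimated correlation). Foxp2 stood at 3.24 ± 0.20 and Tle4 at 2.58 ± 0.13. Receptor genes were also among those that differed. The serotonin receptors Htr1f and Htr2a were higher by 2.08 ± 0.13 and 1.93 ± 0.16. The mu-opioid receptor Oprm1 was higher by 2.67 ± 0.15 and the orexin receptor Hcrtr2 by 2.18 ± 0.22. The glutamate receptors Grik3 and Grm3 were higher by 1.97 ± 0.18 and 1.499 ± 0.13, and the potassium channels Kcnk2 and Kcnh7 by 2.15 ± 0.20 and 1.37 ± 0.10. The cadherin Cdh18 was higher by 2.82 ± 0.12, while Cdh12 stood at -1.13 ± 0.11. The guidance receptors Epha4 and Dcc stood at -1.69 ± 0.17 and -0.87 ± 0.11, and the mineralocorticoid receptor Nr3c2 at -0.73 ± 0.13. The astrocyte transporter Slc1a2 stood at 2.11 ± 0.12 and the oligodendrocyte precursor gene Lhfpl3 at 2.26 ± 0.14, while no glial list passed. The edgeR adjusted p values of these genes were 5.2e-11 to 0.000765.

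The other lists with members named for excitatory nuclei did not pass. As genes higher and lower of those tested, with counts adjusted over the list alone in parentheses, the receptor lists had serotonin and noradrenaline receptors 3 and 0 of 8 (4 and 1), neuropeptide and opioid receptors 3 and 6 of 15 (3 and 7), NMDA and metabotropic glutamate receptors 2 and 4 of 12 (3 and 5) and AMPA and kainate receptors 4 and 2 of 15 (the same) (camera adjusted p 0.140 to 0.957). In the same form the lists of channels, adhesion and guidance had potassium channels 6 and 5 of 27 (7 and 5), synaptic adhesion genes 12 and 8 of 32 (13 and 9) and axon guidance genes 7 and 15 of 29 (9 and 15) (camera adjusted p 0.121 to 0.510). Marker lists and the glucocorticoid list had glucocorticoid response genes 0 and 1 of 9 (the same), astrocyte markers 3 and 1 of 5 (3 and 2), oligodendrocyte markers 0 and 1 of 3 (the same), oligodendrocyte precursor markers 2 and 0 of 3 (the same) and mossy cell markers 0 and 3 of 4 (the same) (camera adjusted p 0.0592 to 0.980).

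5 further lists passed in excitatory nuclei. Lower were the lists of ventral hippocampus (6 of 11 lower and 1 higher, 7 and 1 adjusted over the list alone), of dorsal hippocampus (3 of 5), of subiculum (2 of 3) and of CGE markers (4 of 7). Higher was the direct-pathway list, through Drd1 and its neighbour Sfxn1 at 1.56 ± 0.13. Their camera adjusted p values were 0.00435 to 0.0392, and 0.183 to 0.601 with an estimated correlation. Dcn and Gpc3 stood at -1.98 ± 0.25 and -2.35 ± 0.25, and the mossy cell markers Ajap1 and Csf2rb2 at -1.70 ± 0.19 and -1.997 ± 0.36. 1261 genes passed (683 higher, 578 lower) in the 4 D1 libraries with D2 A and B alone.

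**Figure D4:**
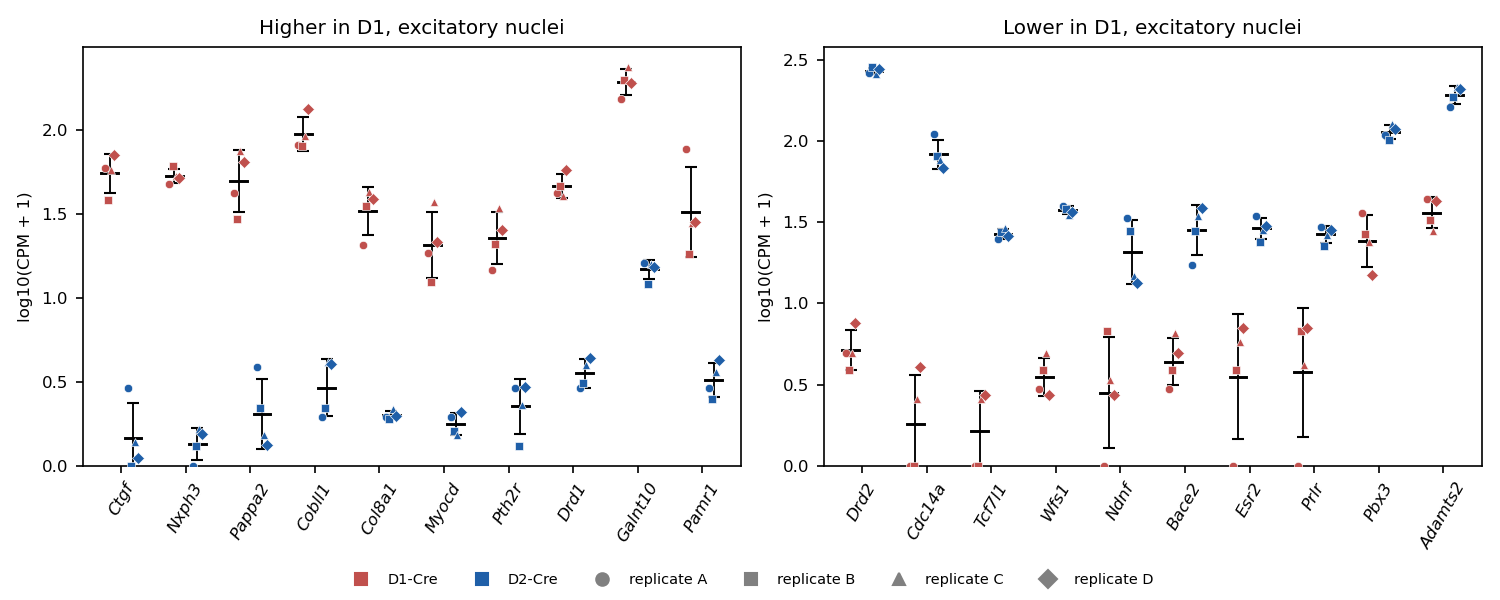
Levels of the 20 genes with the largest differences among those named by the fixed rule in excitatory nuclei, as log10(CPM + 1) (vertical axis) per library and gene (horizontal axis), with D1-Cre in red, D2-Cre in blue, marker shape for the replicate and bars for mean ± SD. Ctgf, at the left of the genes higher in D1, had a mean of 55.9 CPM in D1 and 0.602 CPM in D2.

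Within inhibitory nuclei the same question was asked of interneurons. The lines lay mostly in different clusters, with the MGE and CGE shares given above, so these values also compare clusters. Kit, Egfr, Sv2c and Lamp5 were among the 10 highest genes of a CGE-like cluster with 24 D1 and 930 D2 nuclei. Of 9997 genes tested, 1380 passed, 715 higher and 665 lower in D1. Eya4, a transcriptional coactivator and phosphatase, was higher by 2.44 ± 0.16 (75.7 ± 8.63 against 12.3 ± 5.33 CPM). Brinp3, a neuronal gene of the BMP/retinoic acid-inducible family, was higher by 2.02 ± 0.12 (519.8 ± 84 against 128 ± 5.90 CPM). Tll1, a metalloprotease, was higher by 1.92 ± 0.18 (70.8 ± 19.5 against 21.3 ± 4.78 CPM). Ndnf, the neurotrophic factor also lower over all nuclei, had a log2 fold change of -3.24 ± 0.18 (7.89 ± 2.76 against 71.4 ± 4.76 CPM). The receptor tyrosine kinases Kit and Egfr stood at -3.06 ± 0.15 (14.3 ± 4.25 against 109 ± 13 CPM) and -2.81 ± 0.17 (15.1 ± 4.26 against 109.7 ± 21.2 CPM). Sv2c, a synaptic vesicle glycoprotein, had a log2 fold change of -2.43 ± 0.16 (15.9 ± 2.44 against 79.4 ± 14 CPM). Slc35d2, a nucleotide sugar transporter, was higher by 2.28 ± 0.23 (31.1 ± 6.70 against 8.41 ± 4.56 CPM). By edgeR, adjusted p values were 3.68e-11 to 1.4e-06, without overlap between the lines. Cyp2c66, a cytochrome P450 with close paralogs that can share reads, was higher by 3.28 ± 0.31 (edgeR adjusted p 5.96e-07).

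Axon guidance genes shifted down in inhibitory nuclei (3 higher and 13 lower of 28 tested, 7 higher and 19 lower adjusted over the list alone; camera adjusted p 0.00949, and 0.406 with an estimated correlation). Epha4 stood at -1.23 ± 0.15 and Sema3e at -1.23 ± 0.15. Sema3c was higher by 1.35 ± 0.16, a call that ended after plateau subtraction in 6 libraries, at 1.01 ± 0.33 (edgeR adjusted p 0.0882). Without subtraction these gave 1.18 ± 0.24 (0.00193). Subtraction took Grm7 from -0.79 to -0.06 (0.912). The CGE markers Lamp5 and Nr2f2 stood at -1.90 ± 0.23 and -1.24 ± 0.19. The potassium channel genes Kcnip4 and Kcnd3 stood at -1.19 ± 0.14 and -0.73 ± 0.10, and the glutamate receptor Grm8 at -1.12 ± 0.14. Adhesion genes Cdh13 and Cntnap2 were higher by 0.99 ± 0.14 and 0.81 ± 0.10. Ventral hippocampus genes were lower (4 lower of 6 tested, 1 higher and 4 lower adjusted over the list alone; camera adjusted p 0.00386, and 0.406 with an estimated correlation), and included Gpc3 at -1.99 ± 0.29 and Dcn at -2.02 ± 0.42, the latter with overlap between the lines. Mitochondrially encoded transcripts, a sign of cytoplasmic carry-over in nuclei, were lower (2 lower of 11 tested, 3 lower adjusted over the list alone; camera adjusted p 0.0358, and 0.653 with an estimated correlation). Of these, mt-Co3 stood at -1.41 ± 0.33 and mt-Atp6 at -1.37 ± 0.32, with overlap between the lines and no call by DESeq2. The excitatory marker Camk2a stood at -0.58 ± 0.11. The edgeR adjusted p values of these genes were 9.23e-06 to 0.00639. Higher and lower members of lists that did not pass (adjusted over the list alone in parentheses) had CGE markers 0 and 3 of 7 (the same), NMDA and metabotropic glutamate receptors 0 and 3 of 11 (the same), potassium channels 7 and 9 of 27 (8 and 11) and synaptic adhesion genes 9 and 3 of 32 (13 and 6) (camera adjusted p 0.0975 to 0.517).

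3 other lists passed in inhibitory nuclei, those of excitatory neuron markers, striatal neuron markers and indirect-pathway genes. Their camera adjusted p values were 0.00340 to 0.0358, and 0.406 with an estimated correlation. Each had 2 genes lower and 0 higher of 5 tested (list alone the same), and the indirect-pathway list included Drd2, by whose driver the nuclei were sorted, and its neighbour Ttc12 at -5.16 ± 0.48. 629 genes passed (260 higher, 369 lower) in the 4 D1 libraries with D2 A and B alone. Leaving out D2 C left 909 genes.

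MGE interneuron-like nuclei were compared to ask how far the difference held inside 1 interneuron lineage. Its clusters, given below for the Pvalb and Sst sets, were filled mostly by 1 line each, so the values also compare clusters. Of 9199 genes tested, 828 passed, 431 higher and 397 lower in D1. Rai14, an actin-associated protein, was higher by 2.85 ± 0.41 (26.4 ± 13.9 against 2.66 ± 2.00 CPM). Slc35d2, the nucleotide sugar transporter, was higher by 2.60 ± 0.29 (25 ± 7.15 against 4.54 ± 2.36 CPM). Slc26a4, an anion exchanger, had a log2 fold change of -2.32 ± 0.32 (5.88 ± 1.15 against 40.7 ± 25.1 CPM). Slc24a4, a sodium and calcium exchanger, had a log2 fold change of -2.20 ± 0.26 (5.63 ± 1.41 against 25.7 ± 5.46 CPM). Adamts2, a procollagen proteinase, had a log2 fold change of -2.26 ± 0.30 (5.80 ± 1.78 against 29.9 ± 8.56 CPM). The semaphorin Sema6d was higher by 1.30 ± 0.12 and the potassium channel Kcnh7 by 0.88 ± 0.11. The adhesion genes Cntnap2 and Cntn5 were higher by 1.13 ± 0.12 and 0.95 ± 0.11. Kcnip4 stood at -1.23 ± 0.15, Grm8 at -1.17 ± 0.14 and Gpc3 at -1.92 ± 0.33. All 12 genes had edgeR adjusted p values of 4.96e-07 to 0.000528.

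The axon guidance list shifted down in MGE nuclei (2 higher and 6 lower of 26 tested, 3 higher and 12 lower adjusted over the list alone; camera adjusted p 0.0151, and 0.456 with an estimated correlation). Indirect-pathway genes were lower (3 lower of 5 tested, the same number adjusted over the list alone; camera adjusted p 0.000425, and 0.316 with an estimated correlation), a list that holds Drd2, the gene of the driver, and its neighbour Ttc12, so this restates the sort. Ventral hippocampus genes were lower (3 lower of 6 tested, 1 higher and 4 lower adjusted over the list alone; camera adjusted p 0.00208, and 0.316 with an estimated correlation). Markers of oligodendrocyte precursors were higher (3 higher of 3 tested, the same number adjusted over the list alone; camera adjusted p 0.00482, and 0.316 with an estimated correlation). Lhfpl3 among them was higher by 0.88 ± 0.11 (edgeR adjusted p 2.71e-05). After plateau subtraction in 6 libraries it stood at 0.66 ± 0.19 (adjusted p 0.0882), against 0.96 ± 0.15 (0.00038) without it. Slit3, Htr1f, Grik3 and Zbtb16 did not pass there either (0.0792 to 0.598). Lists without a pass, again as higher and lower members (list alone), had NMDA and metabotropic glutamate receptors 0 and 2 of 11 (1 and 3), potassium channels 4 and 5 of 27 (7 and 6) and synaptic adhesion genes 10 and 4 of 32 (11 and 5) (camera adjusted p 0.0580 to 0.315). Mitochondrially encoded genes were lower (2 lower of 11 tested, 3 lower adjusted over the list alone; camera adjusted p 0.0102, and 0.512 with an estimated correlation). 3 other lists passed, as higher and lower members (list alone) excitatory neuron markers 0 and 2 of 5 (the same), serotonin and noradrenaline receptors 2 and 0 of 8 (5 and 0) and glucocorticoid response genes 0 and 1 of 8 (the same), with camera adjusted p values of 0.0244 to 0.0434 and 0.316 to 0.368 with an estimated correlation. 348 genes passed (148 higher, 200 lower) in the 4 D1 libraries with D2 A and B alone. Leaving out 1 library left 540 without D1 C, 492 without D2 C and 531 without D2 D.

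The Pvalb clusters, a set added after the clusters were seen, were compared to ask the same of 1 interneuron type. The D1 nuclei fell mainly in one cluster (1745 D1 and 51 D2 nuclei) and the D2 nuclei in another (23 D1 and 1047 D2 nuclei). Of 7979 genes tested, 518 passed, 294 higher and 224 lower in D1. Eya4, the coactivator also higher in all inhibitory nuclei, was higher by 3.64 ± 0.25 (88.9 ± 15.4 against 5.61 ± 4.23 CPM). Sntb1, a syntrophin that anchors membrane proteins, was higher by 2.74 ± 0.45 (25 ± 13.1 against 2.31 ± 2.31 CPM). Slc24a4, the calcium exchanger, had a log2 fold change of -2.50 ± 0.36 (5.47 ± 2.67 against 28.6 ± 5.07 CPM). Cpne9, a copine, had a log2 fold change of -2.36 ± 0.42 (3.77 ± 3.98 against 24.6 ± 7.85 CPM). Asb2, a ubiquitin ligase subunit, had a log2 fold change of -2.22 ± 0.38 (3.54 ± 3.28 against 20.7 ± 4.76 CPM). The adhesion genes Cdh13, Cntn5 and Tenm1 were higher by 1.38 ± 0.15, 1.23 ± 0.13 and 1.18 ± 0.14. Sema6d was higher by 2.04 ± 0.14, Kcnh7 by 0.83 ± 0.12 and Hcrtr2 by 1.49 ± 0.34, while Kcnip4 stood at -1.51 ± 0.16. By edgeR, adjusted p values were 3.89e-11 to 0.00544, and no gene overlapped between the lines.

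Synaptic adhesion genes were higher in the Pvalb clusters of D1 (11 higher and 2 lower of 31 tested, 11 higher and 3 lower adjusted over the list alone; camera adjusted p 0.00582, and 0.430 with an estimated correlation). Axon guidance genes were lower (1 higher and 7 lower of 25 tested, 4 higher and 10 lower adjusted over the list alone; camera adjusted p 0.0226, and 0.430 with an estimated correlation). Serotonin and noradrenaline receptor genes were higher (3 higher of 8 tested, the same number adjusted over the list alone; camera adjusted p 0.0226, and 0.430 with an estimated correlation). Oligodendrocyte precursor markers were higher (3 higher of 3 tested, the same list alone, camera adjusted p 0.00106, and 0.369 with an estimated correlation). Lhfpl3 was higher by 1.48 ± 0.15 and, in 6 libraries, 1.17 ± 0.21 (edgeR adjusted p 0.000105). After plateau subtraction there it stood at 0.93 ± 0.30 (0.137). The list members Htr7, Slit3, Zbtb16 and Meis2 did not pass there either (0.648 to 0.769). In the Pvalb clusters the lists that did not pass, as higher and lower members (list alone), had neuropeptide and opioid receptors 2 and 0 of 6 (the same) and potassium channels 1 and 5 of 26 (4 and 6) (camera adjusted p 0.109 to 0.358). Mitochondrially encoded genes were lower (2 lower of 11 tested, 7 lower adjusted over the list alone; camera adjusted p 0.00582, and 0.520 with an estimated correlation). 3 other lists passed, as higher and lower members (list alone) excitatory neuron markers 0 and 2 of 4 (the same), immediate early genes 0 and 0 of 6 (0 and 1) and glucocorticoid response genes 0 and 1 of 7 (the same), with camera adjusted p values of 0.00582 to 0.0364 and 0.369 to 0.430 with an estimated correlation. 244 genes passed (106 higher, 138 lower) in the 4 D1 libraries with D2 A and B alone. Leaving out 1 library left 298 without D2 C and 299 without D2 D.

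The Sst clusters, added in the same way, also split by line, with 880 D1 and 109 D2 nuclei in one cluster and 59 and 987 in the other. Of 6161 genes tested, 417 passed, 225 higher and 192 lower in D1. Pard3b, a cell polarity gene, was higher by 2.68 ± 0.22 (210.1 ± 49.6 against 31.8 ± 14.1 CPM). Brinp3, the gene also higher in all inhibitory nuclei, was higher by 2.37 ± 0.15 (714 ± 131 against 142 ± 18.8 CPM). Slc26a4, the anion exchanger, had a log2 fold change of -2.74 ± 0.44 (5.05 ± 3.25 against 38 ± 16.3 CPM). Palmd, a palmdelphin, had a log2 fold change of -3.06 ± 0.52 (3.82 ± 3.60 against 24.9 ± 4.22 CPM). Meis2, a homeobox transcription factor, had a log2 fold change of -2.34 ± 0.31 (15 ± 10.4 against 82.2 ± 22 CPM). Dab2, an endocytic adaptor, had a log2 fold change of -2.08 ± 0.36 (6.72 ± 4.59 against 32.3 ± 8.07 CPM). Eya4 was higher by 2.30 ± 0.26, Cntnap2 by 1.29 ± 0.13, Sema6d by 1.404 ± 0.14, Erbb4 by 1.29 ± 0.13 and the synaptic organizer Il1rapl1 by 0.92 ± 0.12. Kcnd3 stood at -0.75 ± 0.12. In the Sst clusters lists with members named here that did not pass had axon guidance genes 3 and 5 of 23 (4 and 8), potassium channels 3 and 3 of 26 (4 and 4), synaptic adhesion genes 11 and 4 of 30 (11 and 7) and striatal neuron markers 0 and 1 of 5 (the same) (camera adjusted p 0.154 to 0.794), as higher and lower members (list alone). All 12 genes had edgeR adjusted p values of 1.49e-12 to 0.000253.

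Inhibitory neuron markers were higher in the Sst clusters of D1 (3 higher of 7 tested, 4 higher adjusted over the list alone; camera adjusted p 0.0136, and 0.342 with an estimated correlation). Direct-pathway genes shifted up (2 higher and 1 lower of 3 tested, the same number adjusted over the list alone; camera adjusted p 0.00447, and 0.342 with an estimated correlation), but of the 3 tested 1 was Drd1, the gene of the driver, and 1 its neighbour Sfxn1, so this restates the sort; the indirect-pathway list named below held Drd2. Mitochondrially encoded genes were lower (2 lower of 11 tested, 1 higher and 3 lower adjusted over the list alone; camera adjusted p 0.0216, and 0.612 with an estimated correlation). 2 other lists passed, as higher and lower members (list alone) excitatory neuron markers 0 and 2 of 3 (the same) and indirect-pathway genes 0 and 1 of 3 (0 and 2), with camera adjusted p values of 0.0136 to 0.0216 and 0.342 with an estimated correlation. Among 6114 genes tested in both the Pvalb and the Sst clusters, 104 were higher in D1 in both (independent lists of these sizes would share 8.9) and 91 were lower in both (5.7). Both used the same 8 libraries, which can give part of this overlap. 175 genes passed (86 higher, 89 lower) in the 4 D1 libraries with D2 A and B alone. Of list members, Camk2a, Cdh18 and Slit3 did not pass there after subtraction (edgeR adjusted p 0.0926 to 0.616). Leaving out 1 library left 255 without D1 C, 237 without D2 C and 263 without D2 D.

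CGE interneuron-like nuclei were compared to ask the question of another interneuron lineage. Here too the lines lay mostly in different clusters, with 24, 114 and 288 D1 nuclei against 930, 695 and 76 D2 nuclei, so the values also compare clusters. Egfr was among the 10 highest genes of the first of these clusters and Cnr1, Npas1 and Sema3c among those of the last. Of 4409 genes tested, 745 passed, 416 higher and 329 lower in D1. Ttn, the gene of the giant muscle protein titin, was higher by 4.15 ± 0.41 (143 ± 93.9 against 13 ± 11.3 CPM). Enpp2, the secreted enzyme autotaxin, was higher by 3.00 ± 0.20 (193 ± 41 against 22.2 ± 6.83 CPM). Megf10, an engulfment receptor, was higher by 2.86 ± 0.32 (100.6 ± 41 against 15.6 ± 9.70 CPM). Egfr, the receptor tyrosine kinase, had a log2 fold change of -2.69 ± 0.25 (32.9 ± 14.7 against 231 ± 52.4 CPM). Unc13c, a vesicle priming factor, had a log2 fold change of -2.86 ± 0.43 (7.06 ± 5.22 against 58.8 ± 10.9 CPM). Gcnt2, a glycosyltransferase, had a log2 fold change of -2.65 ± 0.40 (10.2 ± 9.91 against 80.1 ± 17.1 CPM). Cilp2, a matrix protein, was higher by 4.60 ± 0.42, and Parm1 stood at -2.89 ± 0.28. Sema3c was higher by 2.46 ± 0.22, the cannabinoid receptor Cnr1 by 1.69 ± 0.13, the transcription factor Npas1 by 1.48 ± 0.15, the serotonin receptor Htr2c by 1.48 ± 0.18 and the channel subunit gene Kcnip1 by 1.31 ± 0.14. Sema5a stood at -1.87 ± 0.24 and the glutamate receptor Grin2a at -1.33 ± 0.12. Markers of striatal or extended-amygdala neurons were lower (3 lower of 4 tested, 4 lower adjusted over the list alone; camera adjusted p 0.00697, and 0.402 with an estimated correlation). These included the transcription factors Meis2 at -2.65 ± 0.34 and Bcl11b at -1.22 ± 0.23. Among CGE nuclei the lists that did not pass had axon guidance genes 3 and 11 of 23 (4 and 12), CGE markers 4 and 2 of 6 (the same), neuropeptide and opioid receptors 1 and 0 of 4 (1 and 1), NMDA and metabotropic glutamate receptors 1 and 4 of 11 (the same), potassium channels 5 and 2 of 23 (7 and 4) and serotonin and noradrenaline receptors 2 and 2 of 6 (2 and 3) (camera adjusted p 0.0767 to 0.575), as higher and lower members (list alone). Across the genes named, edgeR adjusted p values were 1.57e-11 to 0.000242. 451 genes passed (244 higher, 207 lower) in the 4 D1 libraries with D2 A and B alone.

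CA1-like nuclei, with 3 D1 libraries against 4 D2 libraries because D1 B held too few, were compared to ask how the nuclei given this name differed. The lines lay mostly in different clusters of that name: 1 cluster held 208 D1 and 433 D2 nuclei, and the others 22, 2 and 28 D1 nuclei and 1258, 1191 and 347 D2 nuclei, so the values below also compare clusters. Of 7010 genes tested, 517 passed, 269 higher and 248 lower in D1. Rorb, a nuclear receptor of cortical layers, was higher by 4.11 ± 0.21 (269 ± 30.9 against 14.2 ± 3.83 CPM). Hs3st2, a heparan sulfate sulfotransferase, was higher by 3.15 ± 0.26 (166 ± 49.1 against 17.5 ± 6.36 CPM). Tmem91, a transmembrane protein, was higher by 3.02 ± 0.36 (114 ± 61.3 against 15.1 ± 4.12 CPM). Wfs1, the CA1 marker, had a log2 fold change of -2.85 ± 0.43 (7.57 ± 6.81 against 68.8 ± 2.58 CPM). Meis2, the homeobox gene, had a log2 fold change of -2.73 ± 0.25 (52.8 ± 17.3 against 346 ± 48.9 CPM). Tcf7l1 and Prlr had 0 CPM in the 3 D1 libraries and 46.6 ± 7.60 and 38.3 ± 6.68 CPM in D2. Grik3 was higher by 2.07 ± 0.20, Kcnh7 by 1.01 ± 0.14 and Cdh18 by 1.43 ± 0.17, while Epha4 stood at -1.94 ± 0.24 and the adhesion gene Cntnap5b at -1.72 ± 0.22. Adjusted p values by edgeR were 4.51e-11 to 0.000128 for the 10 genes with a fold change. The lists with members named for CA1-like nuclei had AMPA and kainate receptors 4 and 0 of 14 (5 and 1), axon guidance genes 3 and 8 of 25 (4 and 8), CA1 markers 0 and 1 of 5 (the same), potassium channels 6 and 4 of 25 (8 and 6), synaptic adhesion genes 6 and 6 of 31 (12 and 8), striatal neuron markers 0 and 1 of 5 (the same) and upper or middle cortical layer markers 2 and 1 of 3 (the same) (camera adjusted p 0.0972 to 0.613), as higher and lower members (list alone). No list passed with camera: the smallest adjusted p was 0.0972, 3 lists had an unadjusted p under 0.05, and with an estimated correlation 0 lists passed (smallest adjusted p 0.807). 534 genes passed (253 higher, 281 lower) in the D1 libraries with D2 A and B alone. Leaving out D1 D left 208 genes.

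The last comparison asked whether the difference between the lines differed between excitatory and inhibitory nuclei. In each class the lines lay mostly in different clusters, so these values also compare clusters. Of 10955 genes tested over the 2 classes, 1217 had a different D1 minus D2 difference, 732 with a larger and 485 with a smaller value in excitatory nuclei (edgeR interaction test). 277 genes were higher in D1 in both classes (independent lists would share 62.4 of 9565 tested) and 307 lower in both (56.2), with the same libraries on both sides. 41 genes passed in opposite directions. The 5 with the largest difference between classes were picked after their values were seen. In excitatory and then inhibitory nuclei Eln (elastin) stood at 1.74 ± 0.30 and -1.30 ± 0.40. The netrin receptor Unc5b stood at -1.84 ± 0.28 and 1.45 ± 0.30. Ryr1, a calcium release channel, stood at -1.56 ± 0.42 and 1.74 ± 0.29. The histamine receptor Hrh1 stood at 1.64 ± 0.18 and -1.51 ± 0.28. The mechanosensitive channel Piezo1 stood at 0.94 ± 0.22 and -2.16 ± 0.37. The edgeR adjusted p values of these differences were 3.53e-09 to 1.6e-05. Mean CPM of Eln and Piezo1 were at most 11.8 and 14.1, below the 20 CPM of the naming rule. In the 4 D1 libraries with D2 A and B, 679 genes passed.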

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

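The tests of the deeper D2 libraries, of depth, of free RNA as the source of Drd2 and of the gene minimum were chosen after the result was seen, as were the Pvalb and Sst sets, while the tests of free RNA in the Pvalb clusters and of extra copies were written before their result was seen. The Pvalb test of the deeper libraries was first written and run over the edgeR fold changes of the genes still tested and then, with that result known, computed over all called genes as given here; the outcome against the bounds set beforehand was the same. A first test of depth by thinning was dropped, since thinning leaves the expected ratio as it is, and replaced by the one given here with its value already known.

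19 of 347 groups of 4 libraries held a library whose gap to the nearest other one, divided by the range of the group, was above Dixon's critical value for 4 values at the 0.05 level; chance alone gives about 1 in 20 groups. The share of CA1-like nuclei among excitatory ones was 4.19% in D1 B against 10.7 to 12% in the other D1 libraries. In all nuclei, these were Ndnf at 50.1 CPM in D2 B (others 38 to 39.4), Nr2f2 at 25.3 CPM in D1 D (others 17.8 to 18.9) and Sfxn1 at 41.2 CPM in D2 B (others 35.4 to 35.9). In inhibitory nuclei, this was Xlr5a at 19.5 CPM in D1 B (others 30.4 to 32.4). In MGE nuclei, these were Slc35d2 at 35.6 CPM in D1 A (others 20.1 to 22.7), Slc26a4 at 78.3 CPM in D2 A (others 26.6 to 30.7), Gpc3 at 39.2 CPM in D2 A (others 15.9 to 19), Kcnh7 at 642 CPM in D1 B (others 759 to 774) and Grm8 at 396 CPM in D2 B (others 324 to 333). In CGE nuclei, this was Enpp2 at 131 CPM in D1 A (others 210.2 to 216). In the Pvalb clusters, these were Sntb1 at 44.5 CPM in D1 A (others 16.3 to 20.6), Cdh13 at 753 CPM in D1 A (others 1124 to 1156), Lhfpl3 at 96.7 CPM in D2 B (others 61.5 to 66) and Hcrtr2 at 12.3 CPM in D1 D (others 25.9 to 26.5). In the Sst clusters, these were Slc26a4 at 62.3 CPM in D2 A (others 27.4 to 33.2) and Meis2 at 115 CPM in D2 B (others 68.4 to 72.8). In excitatory nuclei, these were Gpc3 at 22.6 CPM in D2 B (others 28.6 to 29.7) and Cdh18 at 221 CPM in D2 A (others 188 to 192).

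As given above, 1217 genes passed the edgeR interaction test of excitatory against inhibitory nuclei. The excitatory minus inhibitory log2 fold change was 3.18 ± 0.50 for Eln, -3.14 ± 0.42 for Unc5b and -3.13 ± 0.32 for Ryr1. It was 3.03 ± 0.30 for Hrh1 and 3.00 ± 0.46 for Piezo1. These values come from one model over both classes, so they are not exactly the difference of the 2 separate fold changes.

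The barcodes past UMI rank 8000 carried the receptor gene of their own line above its level in the other line. Drd2 stood at 212 CPM in D2 A and 208 CPM in D2 B, against 3.33 to 4.98 CPM in the D1 libraries. Drd1 stood at 13.3, 14.3, 13.6 and 11.8 CPM in D1 A to D, against 0.420 to 0.970 CPM in D2 A and B. Tables of D2 C and D held no such barcodes.

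Within the Pvalb clusters 518 genes differed between the lines, and D1 and D2 nuclei lay mostly in different clusters; the count was 298 without D2 C and 299 without D2 D. Against free RNA as the whole cause, 33.2% of these genes differed in the direction of the plateau and by less (27 to 33.8% leaving out 1 library). Against the deeper D2 libraries and against depth as whole causes, the log2 ratio of mean CPM had a median of 0.878 of its size without D2 C and D (0.837 to 0.885), where D2 A and B had medians of 1417 and 1686 UMIs over all kept nuclei, on either side of the D1 range of 1461 to 1627. Free RNA stays open for the 33.2%, and subtracting the plateau profile left 134 genes against 244 in the same 6 libraries without it. The 2 drivers may mark different Pvalb populations or places within the dissected tissue, a biological explanation that stays an untested hypothesis.

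Drd1 and Drd2 were each high in their own line in nearly every class, as was Sfxn1 beside Drd1, while Ttc12 and Gm4894 beside Drd2 were higher in D2 over all, excitatory and inhibitory nuclei. Plateau UMIs at the plateau level gave 28.5% of Drd2 UMIs in D2 A and B nuclei, against free RNA as their whole source. In the Pvalb clusters, at 43.2 and 51.3%, free RNA stays open. Extra copies of the receptor regions, which a driver transgene could carry, cannot be told apart from higher activity of these regions: 2 of 4 tested neighbours of Drd2 and 1 of 2 of Drd1 were higher in the line of that receptor, too few genes to decide. Hrh2, the other tested neighbour of Drd1, went both ways as given in the report. In CGE nuclei Cplx2, beyond 200 kb, stood at 1.55. Receptor expression by the sorted cells, the biological explanation given by the design, stays open beside both.

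Deep cortical layer-like nuclei made up most excitatory nuclei of D1 and CA1-like nuclei most of those of D2, although the adjusted p did not pass. Against the single gene minimum at unequal depth as the cause, the differences with a library-specific UMI minimum were 1.066 and 1.169 times their size, although D2 C and D, without barcodes past rank 8000, had no such minimum, and against the deeper D2 libraries they were 1.002 and 1.038 times their size without D2 C and D. With classes from marker scores they were 20 and -9.66 points, against 56.4 and -42.1, so the way classes are drawn stays open for most of their size. A difference in dissection between the lines may remain, since nothing in the tables records where a nucleus lay. That the D1 and D2 drivers mark different excitatory populations is the biological explanation, an untested hypothesis.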

How the results depend on the processing

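The tests with a library-specific UMI minimum, all clusters of a name, only the libraries with more than 8000 barcodes, background subtraction and equal depth, and all values of the Pvalb and Sst sets, were chosen after the data were seen. Counts below are genes that passed, with the set of nuclei in parentheses; receptor values are D1 minus D2 in CPM and shares are D1 minus D2 in percentage points. Unless a reason is given, the cause was not tested. The 6 libraries with more than 8000 barcodes give exact p values of 0.0667 or more, so their receptor levels and shares could not pass. The limit of 5000 barcodes removed nothing at 800 genes. DESeq2 size factors and no filter on low counts, run for gene tests only, moved no count by more than 1.5 times. Called doublets kept and all clusters of a name moved no count by more than that and changed no call of a share or receptor level, and no thinning, run for UMI-positive shares only, changed none of these. Class names from marker scores do not exist for the Pvalb and Sst sets, and the interaction was run only without the low-count filter, with DESeq2 size factors, in the 6 libraries and leaving out each library. Shallow libraries limit genes of low level: with at least 1200 genes, D1 A kept 77 nuclei.

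With the DESeq2 Wald test the counts that moved were 821 (inhibitory), 442 (MGE), 492 (CGE), 260 (Pvalb) and 185 (Sst).

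With at least 1200 genes per nucleus, which leaves fewer nuclei, counts fell to 857 (all), 1065 (excitatory), 874 (inhibitory), 439 (MGE), 444 (CGE), 271 (Pvalb) and 118 (Sst). Drd1 differences were 56.4 (all), 32.1 (excitatory), 78.2 (inhibitory), 98.4 (MGE), 63.8 (CGE), 108 (Pvalb) and 82 (Sst) and Drd2 differences -248 (all), -281 (excitatory), -181 (inhibitory), -198 (MGE), -155 (CGE), -251 (CA1-like), -133 (Pvalb) and -262 (Sst), none of which passed (exact permutation, adjusted p 0.0686 to 0.109), nor could they: with at least 20 nuclei MGE, CGE, Pvalb and Sst nuclei had 3 against 3 libraries and CA1-like nuclei 2 against 4, too few to pass, and with these tests in the family of 12 the others could not pass either. The Sst share reversed to -0.737. With at least 500 genes per nucleus the counts rose to 2819 (all) and 732 (Sst), and shares passed with differences of 34.8 (inhibitory), 32.3 (MGE), -32.9 (CGE), -49.5 (CA1-like), -2.16 (Cajal-Retzius), -14.6 (mossy), 59.2 (deep cortical), 3.77 (dentate granule), 25 (Pvalb) and 10.9 (Sst) (adjusted p 0.0286 to 0.0321).

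With the library-specific UMI minimum, counts rose to 2995 (all) and 769 (Sst), and shares passed with 36.3 (inhibitory), 32.9 (MGE), -33.3 (CGE), -49.2 (CA1-like), -2.02 (Cajal-Retzius), -14.7 (mossy), 60.1 (deep cortical), 3.74 (dentate granule), 24.9 (Pvalb) and 11.7 (Sst) (adjusted p 0.0286 to 0.0321). Reversed were MGE Cacna2d1 0.01 and Sst Cacna2d1 0.017, as log2 fold changes that did not pass.

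With classes from marker scores, counts were 786 (excitatory), 507 (MGE), 475 (CGE) and 188 (CA1-like). Shares passed with -11 (excitatory), 19.2 (MGE), -14.5 (CGE), -9.66 (CA1-like), -6.47 (Cajal-Retzius) and 20 (deep cortical) (adjusted p 0.0429), and Drd2 in CA1-like nuclei, at -222, did not and, with 2 D1 against 4 D2 libraries, could not (adjusted p 0.0762). Reversed log2 fold changes, none passing, included excitatory Nectin3 0.13, MGE Vcan -0.138 and CA1-like Cnr1 -0.106, Etv1 -0.132 and Ntng1 -0.292.

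In the libraries with more than 8000 barcodes alone, fewer libraries gave counts of 632 (all), 1261 (excitatory), 629 (inhibitory), 348 (MGE), 451 (CGE), 244 (Pvalb), 175 (Sst) and 679 (the interaction). Drd1 differences were 74.2 (all), 43.1 (excitatory), 102 (inhibitory), 107 (MGE), 63.6 (CGE), 108 (Pvalb) and 107 (Sst) and Drd2 differences -234 (all), -275 (excitatory), -167 (inhibitory), -179.7 (MGE), -146 (CGE), -244 (CA1-like), -139 (Pvalb) and -216 (Sst), with adjusted p 0.0667 to 0.146.

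Background subtraction in the same 6 libraries gave 490 (all), 1036 (excitatory), 349 (inhibitory), 137 (MGE), 309 (CGE), 134 (Pvalb) and 102 (Sst). Reversed log2 fold changes, none passing, were excitatory Nxph1 -0.096, inhibitory Tle4 -0.439, MGE Slc1a2 -1.142, CA1-like Nxph1 -2.172, Pvalb Grm8 0.765 and Slc1a2 -0.771 and Sst Cacna2d1 0.145, Gabra2 0.352, Htr1f -0.032 and Kcnq5 0.302. Equal depth, with fewer UMIs, gave 944 (all), 790 (excitatory), 378 (inhibitory), 179 (MGE), 222 (CGE), 152 (CA1-like), 91 (Pvalb) and 102 (Sst).

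With an estimated correlation the lists that passed numbered 0 (all), 1 (excitatory), 0 (inhibitory), 0 (MGE), 0 (Pvalb) and 0 (Sst), against 13, 6, 6, 8, 8 and 5 with the preset one.

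The replicate letters did not pair the libraries: correlations of same-letter deviations ran from -0.063 to 0.137. D1 A and D2 A matched each other best in 7 of 8 sets, and in no set did every library match its own letter best. With the letter as a replicate block, counts of genes were 1825 (all), 2112 (excitatory), 1421 (inhibitory), 860 (MGE), 765 (CGE), 584 (CA1-like), 529 (Pvalb), 429 (Sst), and 10 lists passed in excitatory nuclei. It moved no other count by more than 1.5 times. The sign-flip test of the block has a smallest p of 0.125, so nothing could pass. There Drd1 differences were 73.5 (all), 42.5 (excitatory), 100.8 (inhibitory), 107 (MGE), 62.3 (CGE), 107 (Pvalb) and 106 (Sst) and Drd2 differences -233 (all), -272 (excitatory), -176 (inhibitory), -195 (MGE), -151 (CGE), -237 (CA1-like), -140.0 (Pvalb) and -246 (Sst) (adjusted p 0.125 to 0.273).

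Leaving out each library in turn, counts ran over 1055 to 2442 (all), 909 to 1843 (inhibitory), 492 to 1165 (MGE), 208 to 689 (CA1-like), 298 to 733 (Pvalb) and 237 to 531 (Sst); the libraries behind the largest moves are named in the report. Shares ran over -20.4 to -6.73 (excitatory), 14.7 to 30.8 (inhibitory), 23.3 to 26.5 (MGE), -27.5 to -25 (CGE), -43 to -40.4 (CA1-like), -17.7 to -13 (mossy), 54.5 to 58.6 (deep cortical) and -1.62 to -0.850 (Cajal-Retzius). Without D1 D all but the Cajal-Retzius share of these passed (adjusted p 0.0367), without D2 A all but the excitatory and inhibitory shares (0.0429), and without any other library none. Values that did not pass but moved by more than 1.5 times were the shares over 1.28 to 3.28 (Sst) and 1.196 to 3.03 (dentate granule) and the receptor difference over 8.46 to 25.3 (Drd1 CA1-like). Receptor differences ran over -241 to -229.8 (Drd2 CA1-like) and 49.1 to 73.6 (Drd1 CGE), and differences in UMI-positive shares over 5.21 to 7.52 (Drd1 CGE) and -20.5 to -19.5 (Drd2 CA1-like) percentage points. Drd1 in CGE nuclei and Drd2 in CA1-like nuclei did not pass in the cases given in the report.

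More genes were higher than lower in D1 in each of the 8 sets, but the side with more was not stable. Without the low-count filter higher and lower genes were 1095 and 1279 (all), 1116 and 1311 (excitatory), 746 and 932 (inhibitory), 473 and 517 (MGE), 348 and 536 (CGE), 243 and 406 (CA1-like), 345 and 303 (Pvalb) and 216 and 236 (Sst). In the 6 libraries, as given in the report, the lower side was larger in inhibitory, MGE, CA1-like, Pvalb and Sst nuclei. It was larger too with DESeq2 in inhibitory (404 and 417), after subtraction in inhibitory (172 and 177), at 500 genes in inhibitory (794 and 842) and MGE (518 and 554), with the UMI minimum in inhibitory (788 and 826) and MGE (521 and 566), at equal depth in all (467 and 477), inhibitory (173 and 205) and CA1-like (75 and 77), without D1 C in CA1-like (168 and 181), without D1 D in all (1068 and 1127) and CA1-like (88 and 120), without D2 C in inhibitory (438 and 471) and MGE (237 and 255), and without D2 D in inhibitory (470 and 505) and MGE (254 and 277).

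By number, results that stayed on their side and that no longer passed were 460 and 67 with DESeq2, 512 and 21 without a filter, 511 and 35 at 500 genes, 399 and 95 at 1200 genes, 248 and 53 with marker scores, 345 and 19 with all clusters of a name, 420 and 125 in the 6 libraries, 308 and 166 after subtraction and 310 and 68 at equal depth.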

Other observations

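All tests in this part were chosen after the results were seen. For each comparison the libraries were split into 2 groups of the same sizes in all 35 ways, and the real split was the only split as large of 35 (1 of 35) in each of the 9. The number of genes in the real split and the highest number in another split were 1862 and 1 for all nuclei, 1916 and 54 for excitatory and 1380 and 86 for inhibitory nuclei. They were 828 and 17 for MGE nuclei, 745 and 109 for CGE nuclei, 517 and 16 for CA1-like nuclei, 518 and 18 for the Pvalb clusters and 417 and 65 for the Sst clusters. For the difference between excitatory and inhibitory nuclei they were 1217 and 137.

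Some nuclei belonged to no compared class. A cluster with CA1 markers (Fibcd1, Mpped1 and Man1a) made up 1.34 to 4.03% of nuclei in D1 and 4.61 to 23.5% in D2 libraries. It was kept out because its 10 highest genes held 1 fibroblast marker and no CA1 one. Dcn was among them, as it was in a kept CA1-like cluster. An unnamed cluster made up 0 to 0.0520% and 0.814 to 10.4%, and a further unnamed one 0 to 0.408% and 0.0810 to 0.897%. The 2 other clusters kept out made up 1.12 to 5.66% and 0.293 to 0.522% in D1 and 0.395 to 0.734% and 0.772 to 1.14% in D2.

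Named clusters were also filled unevenly by the lines. The deep cortical layer-like cluster held 1306 D1 and 46 D2 nuclei, and a mossy cell-like cluster 130 and 1163. CA1-like and CGE-like clusters were uneven too, as given in the report. Plateau barcodes made up most of the 6 larger tables, with a median of 372 to 652 UMIs, and held Gad1 at 91.4 to 210.5 CPM and Slc17a7 at 16.3 to 61.7 CPM.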
